A study of Rattus norvegicus with 6 samples.

How the data were processed

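RNA from sections of 6 rat kidney transplants, 3 tolerated allogeneic and 3 syngeneic, was measured on the Applied Biosystems rat genome survey array, with 1 array per sample. Per the labels' protocols, organs were taken on day 100, total RNA was extracted with TRIzol and cleaned on columns, and 0.5 µg per sample was amplified and labelled with digoxigenin for chemiluminescent detection. The authors deposited a table of raw probe intensity, 1 value per probe and array, and a series matrix of log2 values. The deposited intensity columns had different medians and no sign of normalization between arrays. The scanner software, background subtraction, detection calls and flags behind them are not given in the sources used here, nor is the genome build of the probe design. The deposited log2 columns all had a median of 9.36 and ranked probes exactly as the raw column of the same sample did (rank correlation of 1), as values made equal in distribution between arrays would. Their scale was read from the values as log2, the direction is that of intensity, and no centring of genes was seen; the method behind them is not given in the sources used here. Every column of values belonged to a sample of the series (0 others), and samples were grouped by the titles and source names in the labels.

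The analysis started from the raw intensities. No further background correction was applied, since the signal of this platform is normally corrected by its scanner software; whether that was done here is not stated. Values under 1 would have been set to 1 before log2, and none was that low. Arrays were quantile normalized. Probes were kept if their mean log2 level over all 6 arrays lay above the lower quartile of all probes (7.76), so that 6715 of 26857 probes were removed and 20142 tested. The filter uses the mean over both groups and cannot favour either, but dim transcripts are not covered, and no measure of signal over background was in hand. Where the lower group's mean lay under that threshold, as for Alb, Cthrc1, Klre1, Top2a, C6, Ifng, Ctla4, Ido1 and Alas2, the size of the change rests on a dim level. Quantile normalization assumes equal distributions of levels, so a change of total RNA per cell would not be seen.

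Genes were named only from the platform annotation, of which 6104 probes had 1 symbol, 70 had several and 20683 had none listed. Symbols were updated through Entrez identifiers to the RefSeq gene table of assembly GRCr8, which held 6081 of them. Gene-level statements therefore cover 5041 tested probes of 4955 genes, and a gene with no named probe here may still lie on the array. No coordinates are printed, since the build of the probe design is not known. Where a gene had several tested probes (80 genes), the brightest was used; no gene had probes called in opposite directions, and Ccr1 was the list gene with called and uncalled probes.

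Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), tolerated minus syngeneic, with Benjamini-Hochberg adjustment over all tested probes at 0.05. Errors of log2 fold changes are standard errors of that fit and fold intervals are its 95% confidence intervals. Gene lists (27) were fixed before the data were examined, as were the design, the rule for named genes and the alternatives except those named as chosen later. The 22 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 against the other named genes, with Benjamini-Hochberg adjustment over the lists. Of these, 14 passed as higher and 2 as lower, and none of the 16 passed with an estimated correlation. The estimates reached 0.83 (macrophages and dendritic cells), so for such lists the preset p-values rest on a far lower correlation. With an estimated correlation the unadjusted camera p of the 16 lists was 0.0657 to 0.213, which the adjustment made equal at 0.276. That setting also takes p from the few residual degrees of freedom of the arrays, so a higher p need not mean a high correlation. Fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes, called 17. Each list's members were also counted with adjustment over the list alone. The list of sex-linked genes had no named member here.

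Genes named in the text were the 12 largest increases and 12 largest decreases among probes past the threshold whose 3 values per group did not overlap; up to 4 members per list, those past the threshold with the largest change or, where none passed, the 2 with the smallest p; and 22 genes named whatever their value. Of these 22, 13 were tested, and the others had no named probe in the annotation used here (Cd68 among them) or are not reported here. Cd79b, Lgmn, Cd59b, Prom1, Cldn19, RT1-DOa, Mmp9, Mmp14, Mx2, Ifit3, Rsad2, Ifit1, Cpt1a, Cpt2, Hadhb, Ppargc1a and Ppara were chosen after their values were seen, as the few members that stood apart from their list, as were the clock genes and the examples of gene families. The rule and the clock genes together gave 119 genes. Of these, 108 passed the threshold, and 42 of the 108 did so in each of the 6 fits with 1 array left out. The other genes chosen later are not in these counts.

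The fit was tested on simulated arrays of 20142 independent probes with 200 changed, for tolerated against syngeneic. It recovered 0% of changes of 1 log2 unit (81% at an unadjusted p under 0.05), 50% of changes of 2 and 76% of changes of 3, with 0, 7 and 5 false calls. Camera called 0 of 50 unchanged sets, but these were drawn from independent probes. Estimated correlations in the real lists reached 0.83, so this says nothing about false list calls here. Only 200 probes were changed in the simulation, against 5075 called in the data, and the adjustment is less strict with more changes. The recovered shares therefore do not carry over, though changes of about 1 log2 unit could still be missed with 3 arrays per group.

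The alternatives were median, 75th percentile and cyclic loess scaling, normexp background correction with offset 50, the deposited log2 values, no filter and a filter at the median, a floor of 32, the replicate number as a block, a trended robust prior, array weights, a test without moderation, other thresholds, other list tests and each array left out. Counts of changed list members with each array left out were added after the data had been seen. No dates, slides or batches are given in the sources used here, so no batch could be tested.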

Results

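Gene expression was measured in rat kidney transplants removed on day 100 after transplantation. The samples formed 2 groups of 3 arrays each. Tolerated allogeneic grafts were kidneys of LEW.1W donors (MHC haplotype RT1u) carried by LEW.1A recipients (RT1a) that had been given antibodies against donor class II molecules to induce tolerance. Syngeneic grafts were LEW.1A kidneys carried by LEW.1A recipients. Both strains have the same background genes outside the MHC, the region that encodes the transplantation antigens. Per the labels' protocols, the LEW.1W donor kidneys were 8 to 12 weeks old, and for the allogeneic transplants the recipients' own kidneys were removed on day 7. Donor haplotype, MHC mismatch and antibody treatment differed together between the groups, so their effects cannot be told apart. Each array carried 26857 probes, and its deposited intensities had a median of 760, 745 and 991 in tolerated replicates 1 to 3 and of 421, 538 and 707 in syngeneic replicates 1 to 3. The number of arrays limits the precision, and since nothing stated that the 3 samples of a group came from separate animals, p-values measure the spread between these samples.

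The comparison asked how gene expression in a tolerated, MHC-mismatched kidney differed on day 100 from that in a kidney for which no immune barrier existed. Tolerated grafts had higher levels of macrophage, T cell, interferon-response, MHC, matrix and tubular injury genes, and lower levels of proximal tubule and fatty acid oxidation genes. Each of these 8 lists passed camera with its preset correlation and had adjusted p = 0.276 with an estimated correlation. With 1 array left out, where the fit has fewer samples, fewer single members were mostly called, though list medians kept their sign. The medians ranged from 1.82 to 2.75 for T cell, 2.68 to 3.47 for macrophage and -2.77 to -2.42 for proximal tubule genes. The changed members fell from 15 to 6 for macrophage, 18 to 11 for matrix and 17 to 8 for fatty acid oxidation genes without tolerated replicate 1, 3 and 3, and from 15 to 3 for interferon-response and 16 to 5 for tubular injury genes without syngeneic replicate 2. They fell from 7 to 0 for T cell and 16 to 7 for MHC genes without any 1 of the tolerated replicates, and from 30 to 23 for proximal tubule genes without tolerated replicate 2. Of 15 macrophage and dendritic cell genes tested all 15 rose, with a median log2 fold change of 2.99, and of 36 proximal tubule genes 30 fell, with a median of -2.54. Genes of podocytes, endothelium and the later nephron segments had list medians of -0.20, 0.23 and -0.30. Between the groups, 5075 of 20142 tested probes (25.2%) differed by limma at a Benjamini-Hochberg adjusted p under 0.05, of which 2490 were higher and 2585 lower in tolerated grafts. Among probes with a named gene, 768 genes were higher and 854 lower.

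With 1 array left out the count of probes that differed was 2152, 2030 and 1927 without tolerated replicates 1, 2 and 3, and 2132, 1610 and 6046 without syngeneic replicates 1, 2 and 3. A log2 change of at least 1 was reached by 1821 of the higher and 1783 of the lower probes. The 3 values of each group did not overlap for 47.3% of tested probes, against 10% that chance gives with 3 against 3. The share of higher probes among those called was 49.1%, and 37.5% (1735 higher, 2886 lower) when arrays were scaled to equal medians, which moved the median change of all probes from -0.02 to -0.15.

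Arrays of the same group resembled each other more than arrays of different groups. Pearson correlations of log2 levels across probes were 0.945 to 0.970 within groups and 0.842 to 0.937 between them. The first principal component held 63.2% of the variance and parted the groups. Syngeneic replicate 3 lay nearest to the tolerated grafts, at -32.5 on this component against -107.1 and -104.4 for the other syngeneic arrays and 72.4 to 96.2 for the tolerated ones, and its correlations with the tolerated arrays were 0.904 to 0.937. No pair of arrays was a copy, since at most 0.00745% of probes had equal raw values.

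**Figure D1:**
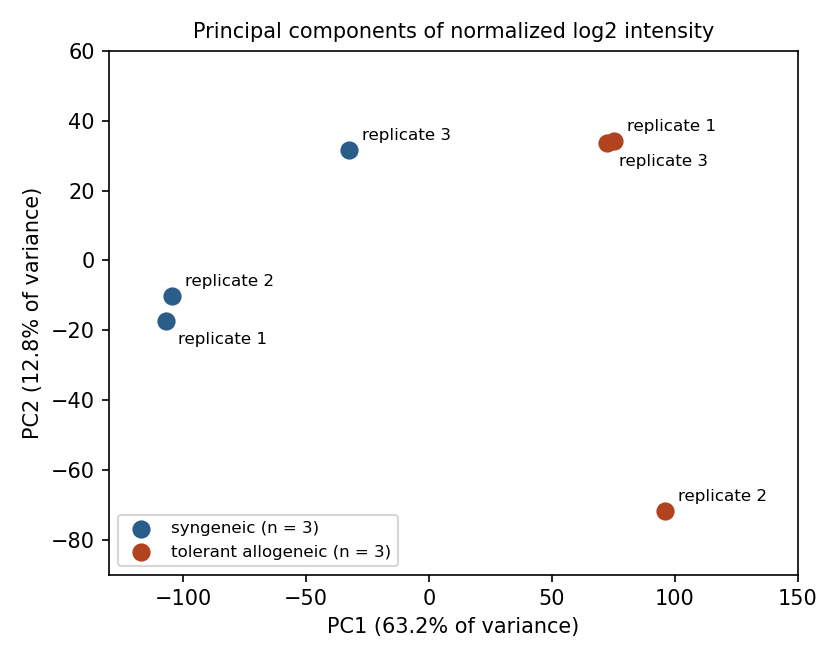
Position of each of the 6 arrays on the first (x axis, 63.2% of variance) and second (y axis, 12.8% of variance) principal component of normalized log2 intensity, with syngeneic arrays in blue and tolerated allogeneic arrays in red. The tolerated arrays lie between 72.4 and 96.2 on the first component, and syngeneic replicate 3, at -32.5, is nearest to them.

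The largest increase was that of A2m, which encodes the protease inhibitor alpha-2-macroglobulin (probe 21660354). Its log2 level was 16.20 ± 0.10 in tolerated and 9.84 ± 1.80 in syngeneic grafts (SD, n = 3 each), an 82.1-fold difference with a 95% interval of 18.7 to 361 (limma, adjusted p = 0.00836). The fold of A2m was 40.3 without syngeneic replicate 2 and 142 without syngeneic replicate 3, so its size is uncertain. Pnoc, the precursor of the neuropeptide nociceptin, rose 47.9-fold (26.7 to 85.9, adjusted p = 0.00363), from 7.80 ± 0.42 to 13.38 ± 0.51 (log2, SD). Lcn2, the iron-binding lipocalin released by injured tubules, rose 35.7-fold (6.69 to 190, adjusted p = 0.018) and the epithelial calcium channel gene Trpv6 rose 30.9-fold (adjusted p = 0.0224). The folds of these 2 were 22.1 and 16.0 without syngeneic replicate 2, and 80.5 and 66.3 without syngeneic replicate 3. Il24, the chemokine gene Cxcl9, the IgG receptor gene Fcgr2b, the matrix-associated Cthrc1, the metalloprotease gene Mmp7, complement C2, the diamine oxidase gene Aoc1 and the lectin gene Reg3b rose between 18.3-fold (Reg3b) and 24.0-fold (Il24). Among them Il24, Cxcl9, Fcgr2b, Mmp7, C2 and Aoc1 had folds of 43.9, 50.7, 44.5, 40.0, 38.7 and 30.1 without syngeneic replicate 3. Lower folds were those of Il24 without syngeneic replicate 1 (13.1) and of Cxcl9, Fcgr2b and C2 without syngeneic replicate 2 (15.9, 12.9 and 13.3). A2m, Pnoc, Cthrc1 and Reg3b passed the threshold with any 1 array left out, and the other 8 did not in at least 1 of the 6 such fits. Lcn2, Trpv6 and Cxcl9 passed only in the fit without syngeneic replicate 3, with adjusted p up to 0.0614, 0.0755 and 0.0705 in the others. C2 is encoded in the MHC, where the donor kidneys differed, so sequence match may add to its change.

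The largest decrease was that of Alb, which encodes albumin (probe 21581708). Its log2 level was 7.03 ± 0.60 in tolerated and 15.26 ± 2.21 in syngeneic grafts (SD, n = 3 each), a fitted fall of 300.2-fold with a 95% interval of 46.3 to 1948 (limma, log2 fold change -8.23 ± 1.10, adjusted p = 0.00786). The tolerated level lay under the filter threshold of 7.76 and its signal over background is not known, and without syngeneic replicate 1 the log2 fold change of Alb was -7.05 and without syngeneic replicate 2 it was -9.22, so the size of the fold is uncertain. In syngeneic replicate 1 Alb stood at 17.66, against 13.32 and 14.79 in replicates 2 and 3, and 25 of 26 transcripts known from liver, a list chosen after the fall of Alb was seen, were higher in replicate 1 than the mean of replicates 2 and 3. Spp2 fell 105-fold (adjusted p = 0.00524), Rgn, the calcium-binding regucalcin, fell 60.5-fold (adjusted p = 0.00421), and Gc, the vitamin D binding protein, fell 45.2-fold (adjusted p = 0.00421). Pck1, the key enzyme gene of glucose synthesis in proximal tubules, fell 42.7-fold (23.8 to 76.8, adjusted p = 0.00363), from 20.54 ± 0.63 to 15.12 ± 0.23 (log2, SD). The retinol dehydrogenase gene Rdh16, the transporter gene Slc22a25, Nat8f1, the histamine-inactivating Hnmt, the carboxylesterase gene Ces1e, the gap junction gene Gjb2 and Gucy1b2 fell between 31.7-fold (Gucy1b2) and 48.7-fold (Rdh16). Of these 12 genes all but Gjb2 passed the threshold with any 1 array left out, and Gjb2 missed it without syngeneic replicate 1 or 2 (adjusted p up to 0.0596) and had a log2 change of -4.06 without tolerated replicate 2, against -5.09 with all arrays.

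Macrophage and dendritic cell genes rose as a group. All 15 tested members were higher (15 also when adjusted over the list alone), led by the IgG receptor genes Fcgr2b (log2 fold change 4.54 ± 0.87, SE) and Fcgr3a (3.81 ± 0.67) and the complement C1q genes C1qc (3.51 ± 0.47) and C1qa (3.50 ± 0.52), which tissue macrophages make. The list passed camera with its preset correlation (adjusted p = 2.38e-07) and had adjusted p = 0.276 with an estimated correlation. C1qc and C1qa passed with any 1 array left out, while Fcgr2b and Fcgr3a did not (adjusted p up to 0.0634 and 0.0569). The log2 changes of Fcgr2b, Fcgr3a and C1qa were 5.47, 4.59 and 4.10 without syngeneic replicate 3, and that of Fcgr2b was 3.69 without syngeneic replicate 2. The mean level of its members, relative to all 6 arrays, was 1.57, 1.44 and 1.47 in the tolerated arrays and -2.11, -1.99 and -0.38 in the syngeneic ones, so that syngeneic replicate 3 lay between. With 1 array left out the risen members numbered 6, 8 and 7 without tolerated replicates 1 to 3, and 11, 8 and 15 without syngeneic replicates 1 to 3.

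T cell genes were higher in tolerated grafts: 7 of 12 tested members rose (11 adjusted over the list alone) and none fell, with a list median of 2.23. The adhesion receptor gene Cd2 (2.88 ± 0.76), Cd8b of the cytotoxic T cell coreceptor (2.64 ± 0.50), the kinase gene Zap70 (2.55 ± 0.71) and Cd3d of the T cell receptor complex (2.46 ± 0.65) led them. Cd2, Zap70 and Cd3d had 3.74, 3.30 and 3.15 without syngeneic replicate 3, and Zap70 had 1.92 without syngeneic replicate 1. Cd4 had 2.18 ± 0.71 (adjusted p = 0.073; 1.42 without syngeneic replicate 1) and Cd8a 1.33 ± 0.49 (adjusted p = 0.100), which passed without syngeneic replicate 2 (1.85, adjusted p = 0.0302). As a list they had a camera adjusted p = 0.00068, and adjusted p = 0.276 with an estimated correlation. Their mean level in syngeneic replicates 1 to 3 was -1.81, -1.10 and -0.10. The number past the threshold was 0 without tolerated replicate 1, 2 or 3 or syngeneic replicate 1, it was 1 without syngeneic replicate 2, and it was 9 without syngeneic replicate 3.

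Among natural killer and cytotoxic cell genes 7 of 13 rose (10 adjusted over the list alone, with 1 lower), and the median was 1.99. The lectin-like receptor genes Klre1 (3.77 ± 0.46), Klrk1 (3.04 ± 0.67) and Klrd1 (2.92 ± 0.48) and the granzyme gene Gzmc (2.69 ± 0.76) led, with 3.79 for Klrk1 and 3.37 for Gzmc without syngeneic replicate 3. Ifng, the gene of interferon gamma, rose by 1.93 ± 0.41 (adjusted p = 0.0242), and Gzmb had 0.99 ± 0.38 (adjusted p = 0.109) but passed without tolerated replicate 2 (1.41, adjusted p = 0.0300). Camera gave the list an adjusted p = 0.000844, and adjusted p = 0.276 with an estimated correlation. Klre1 passed with any 1 array left out, while Ifng was lost without tolerated replicate 1, 2 or 3 or syngeneic replicate 2 (adjusted p up to 0.0834). The risen members numbered 2, 4 and 2 without tolerated replicates 1 to 3, and 3, 1 and 9 without syngeneic replicates 1 to 3.

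Of 5 B cell genes 3 rose (4 adjusted over the list alone), and the list had a camera adjusted p = 0.0167, and adjusted p = 0.276 with an estimated correlation. These were the tetraspanin gene Cd37 (2.58 ± 0.50) and the kinase gene Btk (2.49 ± 0.43), both also expressed by other leukocytes, and the low-affinity IgE receptor gene Fcer2 (2.38 ± 0.24). Cd79b had 3.82 but did not pass (limma adjusted p = 0.0927). Its change was 3.12 and 3.07 without syngeneic replicates 1 and 2, and it passed without syngeneic replicate 3 (5.31, adjusted p = 0.00776). Of the 5 changes 1 was negative. Ms4a1, Cd79a and Ighm had no probe named in the annotation used here. Only Fcer2 passed without tolerated replicate 2 or 3 or syngeneic replicate 2. Of 3 plasma cell genes the syndecan gene Sdc1 rose by 1.53 ± 0.25 (adjusted p = 0.0124), and 3 members were too few for a test of the list.

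Genes that regulate immune responses moved mostly upward, 7 of 13 rising and 1 falling (10 and 1 adjusted over the list alone), with a median of 1.95 (1.36 without syngeneic replicate 1). The inhibitory receptor gene Lag3 rose by 3.15 ± 0.66, the cytokine signalling suppressor gene Socs3 by 2.77 ± 0.48 and Tgfb1 by 2.46 ± 0.46, while Nt5e, an enzyme that forms adenosine and is also made by renal tubules, fell (-2.43 ± 0.47). Ctla4 had a log2 fold change of 1.42 ± 0.40 (adjusted p = 0.0496) and Hmox1 of 1.02 ± 0.25 (adjusted p = 0.0347), Il10 had 1.95 ± 0.67 (adjusted p = 0.0839) and Ido1 1.16 ± 0.66, which did not pass either. Il10 had 1.36 without syngeneic replicate 1 and passed without syngeneic replicate 3 (2.63, adjusted p = 0.0149). Ido1 stood at 10.02 in tolerated replicate 1 against 7.92 and 7.93 in replicates 2 and 3, and without replicate 1 its probe was under the filter. Foxp3 had no named probe. Camera gave an adjusted p = 0.00068, and adjusted p = 0.276 with an estimated correlation. The risen members numbered 3 without tolerated replicate 1, 2 or 3, and 5, 2 and 8 without syngeneic replicates 1 to 3. Tgfb1 and Ctla4 passed only without syngeneic replicate 3 (adjusted p up to 0.0644 and 0.135 in the other fits), and Lag3 only without syngeneic replicate 1, where its change was 2.45, or 3 (up to 0.0740). Socs3 was lost without syngeneic replicate 2 (0.0577), Nt5e without syngeneic replicate 1 or 2 (adjusted p up to 0.0712), and Hmox1 in each of the 6 fits with 1 array left out (up to 0.108).

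MHC-encoded antigen presentation genes rose together, 16 of 17 tested members being higher (17 adjusted over the list alone) with a median of 2.35. RT1-N3, a class Ib gene, rose by 3.13 ± 0.69, the class II gene RT1-Da by 2.97 ± 0.55, and the immunoproteasome subunit genes Psmb9 and Psmb8 by 3.09 ± 0.53 and 2.79 ± 0.55. RT1-DOa, with 2.35 ± 0.67 (adjusted p = 0.052), was the member that did not pass, though it did without syngeneic replicate 3 (3.12, adjusted p = 0.00212). In camera the adjusted p was 2.48e-08, with adjusted p = 0.276 with an estimated correlation. Donor kidneys of the groups differed in RT1 haplotype, so probes of these polymorphic genes can differ in sequence match as well as in transcript level. The median was 2.77 over the 4 members other than RT1 genes. These are also encoded in the MHC, so this value does not part sequence match from transcript level. The risen members of the whole list numbered 7 without tolerated replicate 1, 2 or 3, 9 and 8 without syngeneic replicates 1 and 2, and 17 without syngeneic replicate 3. RT1-N3, RT1-Da, Psmb9 and Psmb8 were each lost in 4 or 5 of these 6 fits, and had log2 changes of 3.94, 3.62, 3.72 and 3.42 without syngeneic replicate 3.

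Of the 11 antigen presentation genes encoded outside the MHC, 4 rose (4 adjusted over the list alone), with a list median of 0.38. These were Ctss, the protease that trims the class II invariant chain (2.42 ± 0.37), Ciita, the class II transactivator (2.19 ± 0.36), Cd74, the invariant chain itself (1.86 ± 0.35), and the peptidase gene Erap1 (1.12 ± 0.23). B2m, the class I light chain, had 0.73 ± 0.27 (adjusted p = 0.104) and passed without syngeneic replicate 3 (1.03, adjusted p = 0.0135). The list's camera adjusted p was 0.0469, with adjusted p = 0.276 with an estimated correlation, and it lay above 0.05 without tolerated replicate 1 (0.0610), tolerated replicate 3 (0.0533) or syngeneic replicate 1 (0.0579) and with median scaling (0.0792), 75th percentile scaling (0.0680) or the stricter filter (0.0637), in a range of 0.0305 to 0.0792 over all settings of this test. Ctss and Ciita passed with any 1 array left out, and 2 members were higher in each such fit except that without syngeneic replicate 3. In that fit 5 were higher and 1, Lgmn, was lower (-0.93, adjusted p = 0.0303). The difference between this list and the MHC-encoded list was not tested.

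Interferon-response genes rose in 15 of 19 tested members (16 adjusted over the list alone), with a median change of 4.01-fold and none falling. Cxcl9 (4.58 ± 0.93) and Cxcl10 (3.39 ± 0.61), chemokines induced by interferon gamma, and the GTPase genes Gbp2 (4.12 ± 0.70) and Ifi47 (3.31 ± 0.60) led. Mx2, Ifit3, Rsad2 and Ifit1 did not pass, with log2 fold changes of 1.93 ± 0.83, 1.49 ± 0.47, 0.68 ± 0.45 and -0.42 ± 0.67. Mx2 had 1.10 without syngeneic replicate 1 and passed without syngeneic replicate 3 (2.67, adjusted p = 0.0423), and Ifit3 passed without tolerated replicate 2 (1.93, adjusted p = 0.0432). Tested with camera, the list had adjusted p = 6.43e-07, and adjusted p = 0.276 with an estimated correlation. Its mean level in syngeneic replicates 1 to 3 was -1.65, -1.43 and -0.24, and the risen members numbered 4, 7 and 5 without tolerated replicates 1 to 3, and 8, 3 and 16 without syngeneic replicates 1 to 3. None of the 4 leading genes passed in all 6 such fits. The log2 changes of Cxcl9, Cxcl10, Gbp2 and Ifi47 were 5.66, 4.06, 4.89 and 4.01 without syngeneic replicate 3, and those of Gbp2 and Cxcl9 were 3.50 without syngeneic replicate 1 and 3.99 without syngeneic replicate 2.

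Chemokine and lymphoid organisation genes rose in 14 of 25 members (19 adjusted over the list alone), with a median of 1.70. The lymphoid chemokine gene Ccl21 (4.10 ± 1.09), Xcl1 (3.95 ± 1.00), the monocyte attractant gene Ccl2 (3.22 ± 0.69) and Ltb, the lymphotoxin beta gene (2.79 ± 0.71), led. Their camera adjusted p was 8.64e-07, and adjusted p = 0.276 with an estimated correlation. The risen members numbered 4 without tolerated replicate 1, 2 or 3 or syngeneic replicate 2, 6 without syngeneic replicate 1 and 17 without syngeneic replicate 3, and none of these 4 genes passed in all 6 fits. Ccl21, Xcl1, Ccl2 and Ltb had log2 changes of 5.27, 5.10, 3.98 and 3.61 without syngeneic replicate 3, and Ccl21 and Xcl1 had 3.06 and 3.30 without syngeneic replicate 2 and Ccl2 had 2.54 without syngeneic replicate 1. Cxcl13 had no named probe. Ltb is encoded in the MHC, where the donor kidneys differed, so its probe can differ in sequence match as well as in transcript level.

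Of 17 complement genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). The median of the complement list was 0.72, but 1.42 without syngeneic replicate 1, 0.50 without syngeneic replicate 3 and 1.25 with the stricter filter on dim probes, so its size is uncertain. C2 of the classical pathway rose by 4.39 ± 0.77, the protease gene C1s by 2.57 ± 0.28, the anaphylatoxin receptor gene C5ar1 by 2.52 ± 0.34 and C6 by 2.31 ± 0.31, while Cd59b, an inhibitor of the membrane attack complex, fell (-0.95 ± 0.24). C2 is itself encoded in the MHC, where the donor kidneys differed, so its probe can differ in sequence match as well as in transcript level. For the list, camera gave adjusted p = 0.00385, and adjusted p = 0.276 with an estimated correlation. C1s, C5ar1 and C6 passed with any 1 array left out and C2 did not (adjusted p up to 0.0540; change 3.73 without syngeneic replicate 2 and 5.27 without syngeneic replicate 3), and the fall of Cd59b was lost without tolerated replicate 2 or 3 or syngeneic replicate 1 or 2, where 0 members were lower. The risen members numbered from 4 (without tolerated replicate 3) to 7 with 1 array left out.

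Extracellular matrix and fibrosis genes rose in 18 of 20 members (18 adjusted over the list alone), with a median of 2.16. Col1a2, a chain of type I collagen, rose by 3.02 ± 0.24, fibronectin (Fn1) by 2.98 ± 0.37, the metalloprotease inhibitor gene Timp1 by 2.96 ± 0.36 and the collagen crosslinking enzyme gene Lox by 2.96 ± 0.27, and these 4 passed with any 1 array left out. Mmp9 (1.15 ± 0.46) and Mmp14 (0.67 ± 0.29) did not pass, and Col1a1 had no named probe. Camera tested the list at an adjusted p = 3.23e-09, and adjusted p = 0.276 with an estimated correlation. Its mean level was 1.01 to 1.07 in the tolerated arrays and -1.36, -1.28 and -0.51 in the syngeneic ones, and the risen members numbered from 11 (without tolerated replicate 3) to 18.

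Tubular injury genes rose in 16 and fell in 2 of 25 members (18 and 2 adjusted over the list alone), with a median of 2.14. Beside A2m, Lcn2 and Mmp7, Havcr1, the injury marker KIM-1 of proximal tubules, rose by 3.47 ± 0.57 (adjusted p = 0.0131). Tff3, a trefoil peptide gene, fell (-3.93 ± 0.38, adjusted p = 0.00422), as did Prom1 (-1.39 ± 0.29, adjusted p = 0.0225). With camera the adjusted p was 0.000202, and adjusted p = 0.276 with an estimated correlation. The risen members numbered 6, 7 and 10 without tolerated replicates 1 to 3, and 9, 5 and 18 without syngeneic replicates 1 to 3. Tff3 passed with any 1 array left out, Prom1 was lost without tolerated replicate 1, 2 or 3 or syngeneic replicate 2, where only 1 member was lower, and Havcr1 missed the threshold without syngeneic replicate 2 (adjusted p = 0.0530).

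**Figure D2:**
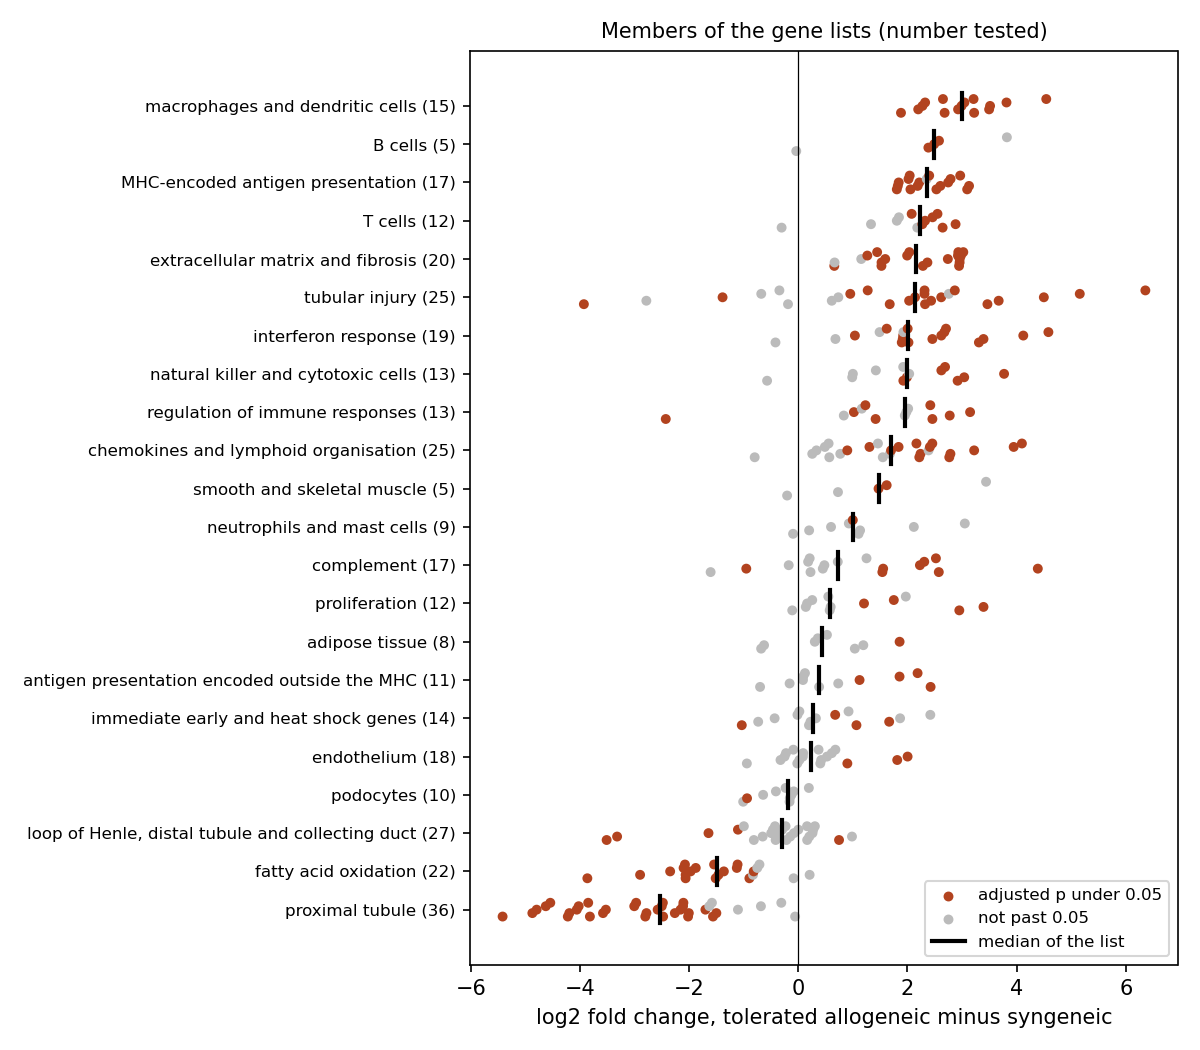
Log2 fold change (x axis, tolerated allogeneic minus syngeneic, 3 arrays each) of each tested member of the 22 tested gene lists (y axis, number of members in brackets), in red where the limma adjusted p is under 0.05 and in grey where it is not, with a black bar at the list median. Macrophage and dendritic cell genes have a median of 2.99 and proximal tubule genes of -2.54, and podocyte, endothelium and later nephron genes have medians of -0.20, 0.23 and -0.30.

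Proximal tubule genes fell in 30 of 36 tested members (33 adjusted over the list alone), none rose, and all 36 had negative changes. Pck1 (-5.42 ± 0.34), Fbp1 (-4.87 ± 0.36) and G6pc1 (-4.63 ± 0.81), enzymes of glucose synthesis, and Slc22a2, an organic cation transporter (-4.79 ± 0.39), had the largest falls. By camera the list's adjusted p was 1.85e-13, and adjusted p = 0.276 with an estimated correlation. Its mean level was -1.19, -1.67 and -1.30 in the tolerated arrays and 1.61, 1.56 and 0.99 in the syngeneic ones. The fallen members numbered 23 to 31 with 1 array left out, and G6pc1 missed the threshold without tolerated replicate 1, 2 or 3 or syngeneic replicate 2 (adjusted p up to 0.0573), with a change of -3.87 without syngeneic replicate 1 and -5.50 without syngeneic replicate 3.

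Fatty acid oxidation genes, which proximal tubules use heavily, fell in 17 of 22 members (20 adjusted over the list alone) with a median of -1.49. The peroxisomal enzyme genes Ehhadh (-3.86 ± 0.32) and Cat (-2.90 ± 0.21), the thioesterase gene Acot1 (-2.35 ± 0.41) and the medium-chain acyl-CoA dehydrogenase gene Acadm (-2.10 ± 0.18) had the largest falls. Cpt1a (-0.83 ± 0.31), Cpt2 (-0.75 ± 0.26), Hadhb (-0.71 ± 0.22), Ppargc1a (-0.09 ± 0.27) and Ppara (0.21 ± 0.60) did not pass, although Cpt1a and Hadhb did without syngeneic replicate 3 (adjusted p = 0.0470 and 0.0339). These genes had a camera adjusted p = 2.48e-07, and adjusted p = 0.276 with an estimated correlation. Ehhadh, Cat and Acadm passed with any 1 array left out, and Acot1 did not (adjusted p up to 0.0555). The fallen members numbered 9, 9 and 8 without tolerated replicates 1 to 3, and 11, 8 and 18 without syngeneic replicates 1 to 3.

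Genes of the loop of Henle, distal tubule and collecting duct did not pass as a list (camera adjusted p = 0.161), with 4 of 27 members lower and 1 higher (4 lower and 0 higher adjusted over the list alone). Klk1, tissue kallikrein (-3.51 ± 0.56, adjusted p = 0.0122), and Egf, epidermal growth factor (-3.32 ± 0.48, adjusted p = 0.00944), fell most, and both passed with any 1 array left out. The pendrin gene Slc26a4 (-1.64 ± 0.34) and Fxyd2, a subunit of the sodium pump (-1.11 ± 0.22), also fell, and the tight junction gene Cldn19 rose by 0.75 ± 0.20 (adjusted p = 0.0463). Slc26a4 and Fxyd2 were lost in 4 of the 6 fits with 1 array left out (adjusted p up to 0.0669 and 0.0743), and the rise of Cldn19 was lost without tolerated replicate 1, 2 or 3 or syngeneic replicate 2, where 0 members were higher. The lower members numbered 2 without tolerated replicate 1 or 2 or syngeneic replicate 2. Without tolerated replicate 3 the camera adjusted p of the list was 0.0411, in a range of 0.0411 to 0.575 over all settings of this test.

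Podocyte genes did not pass as a list (camera adjusted p = 0.291). Of 10 members only Podxl, the surface sialoprotein podocalyxin, fell (-0.94 ± 0.24, adjusted p = 0.0388; none adjusted over the list alone), and it passed with 1 array left out only without syngeneic replicate 3. Endothelial genes did not pass either (camera adjusted p = 0.196), with 3 of 18 members higher (3 adjusted over the list alone). These were Icam1, an adhesion molecule of activated endothelium and leukocytes (4.01-fold, 2.36 to 6.79), the transcription factor gene Ets1 (log2 1.81 ± 0.27) and Icam2 (0.90 ± 0.21). Icam1 and Ets1 passed with any 1 array left out, and Icam2 only without syngeneic replicate 3.

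**Figure D3:**
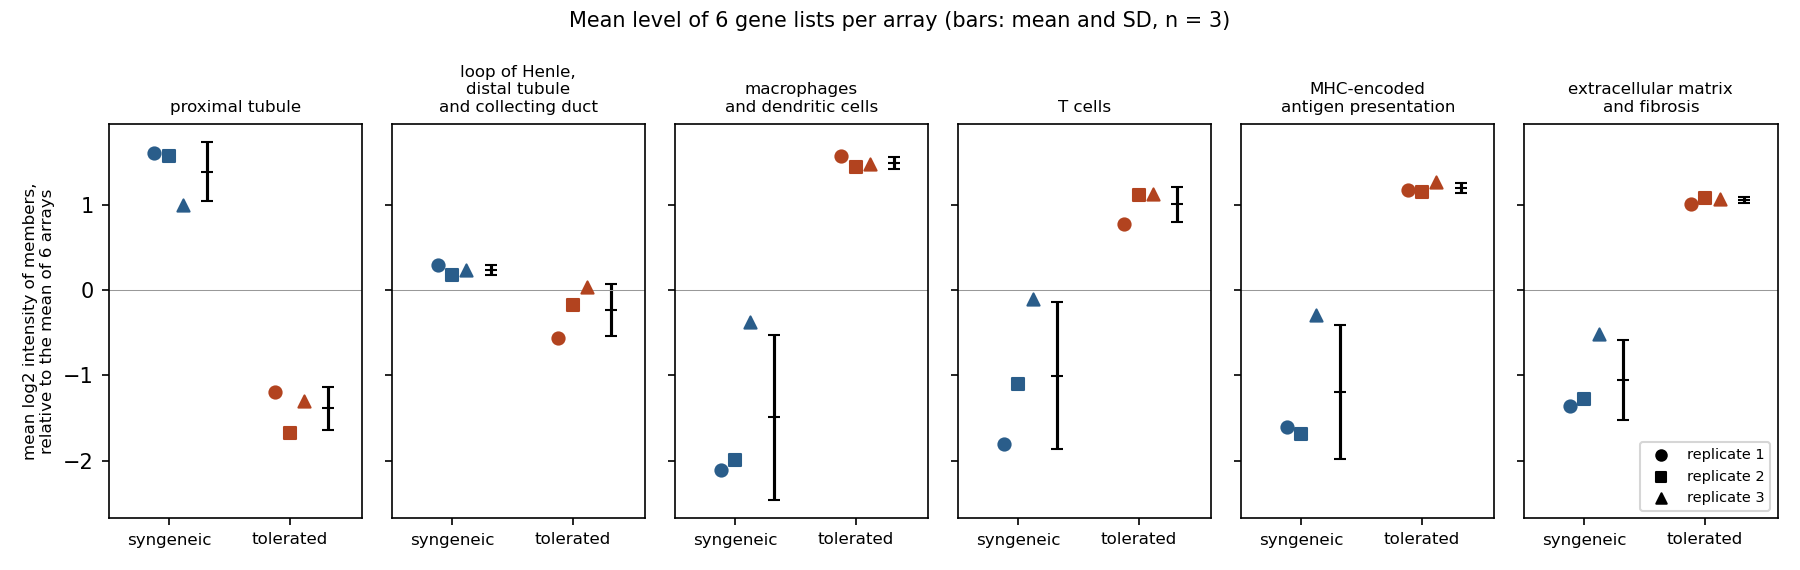
Mean log2 intensity of the members of 6 gene lists in each array (y axis, relative to the mean of all 6 arrays), with 1 symbol per array (circle, square and triangle for replicates 1, 2 and 3) and a bar for mean and SD (n = 3) beside each group. Syngeneic replicate 3 is the syngeneic array nearest to the tolerated arrays for macrophage (-0.38), T cell (-0.10), MHC (-0.29), matrix (-0.51) and proximal tubule (0.99) genes.

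Proliferation genes rose in 4 of 12 members (6 adjusted over the list alone), namely the cell cycle kinase genes Cdk1 (3.39 ± 0.81), Aurkb (1.75 ± 0.36) and Plk1 (1.20 ± 0.30) and the topoisomerase gene Top2a (2.95 ± 0.60). Camera gave them an adjusted p = 0.00617, and adjusted p = 0.276 with an estimated correlation. The number past the threshold was 0 without tolerated replicate 1 or 2, 1 without tolerated replicate 3 or syngeneic replicate 1, 2 without syngeneic replicate 2 and 6 without syngeneic replicate 3. Cdk1 and Top2a had 2.77 and 3.63 without syngeneic replicate 2, and Cdk1 had 4.31 without syngeneic replicate 3. With the stricter filter on dim probes the camera adjusted p was 0.0637, in a range of 0.000998 to 0.0637 over all settings of this test.

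Blood cell, stress and neighbouring tissue markers were also examined. All 3 erythroid genes fell (3 adjusted over the list alone), namely the haemoglobin genes Hbb (-1.95 ± 0.39) and Hbb-b1 (-1.97 ± 0.41) and Alas2, the first enzyme of haem synthesis in red cells (-2.40 ± 0.28). Alas2 passed with any 1 array left out, and 1 of the 3 passed without tolerated replicate 3 or syngeneic replicate 1 or 2. Among neutrophil and mast cell genes S100a9 alone passed (1.00 ± 0.26; none adjusted over the list alone), and the camera adjusted p of 0.0469 became adjusted p = 0.276 with an estimated correlation. It also exceeded 0.05 without tolerated replicate 3 (0.0533) or syngeneic replicate 1 (0.0585) or 2 (0.0514), with normexp correction (0.0581), the stricter filter (0.0655) and a trended prior (0.0593), in a range of 0.0196 to 0.0655 over all settings of this test. S100a9 passed only without syngeneic replicate 1 (adjusted p up to 0.116 in the other fits), and the risen members numbered 0 without tolerated replicate 1, 2 or 3 or syngeneic replicate 2 and 3 without syngeneic replicate 3. Of 14 immediate early and heat shock genes Myc (1.67 ± 0.32), Hspb1 (1.07 ± 0.15) and Jund (0.68 ± 0.16) rose and Hsph1 fell (-1.04 ± 0.20; 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.102). Without syngeneic replicate 2 this camera adjusted p was 0.0230, in a range of 0.0230 to 0.345 over all settings of this test, and the list's median of 0.27 was -0.04 with median scaling. Hspb1 passed with any 1 array left out, Myc was lost without syngeneic replicate 1 or 2 (adjusted p up to 0.0687), Hsph1 without tolerated replicate 1 or 2 or syngeneic replicate 1 or 2 (up to 0.0680), and Jund in all fits except that without syngeneic replicate 3 (up to 0.109).

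Des (1.62 ± 0.32) and Cnn1 (1.47 ± 0.27), both genes of contractile cells, rose among 5 muscle genes (3 adjusted over the list alone; camera adjusted p = 0.0695). This p was 0.0236 with median scaling, 0.0302 with 75th percentile scaling and 0.0323 without syngeneic replicate 2, in a range of 0.0236 to 0.136 over all settings of this test, and fry gave 0.00620. No muscle gene passed without tolerated replicate 1 or 3. Fabp4 was the member that rose among 8 adipose genes (1.86 ± 0.47; none adjusted over the list alone; camera adjusted p = 0.270), and it passed with 1 array left out only without syngeneic replicate 2 (adjusted p up to 0.110 in the other fits). The 2 urothelial genes Krt15 (3.58 ± 1.30, adjusted p = 0.0968) and Krt13 (0.26 ± 0.20) and the 4 adrenal genes did not pass. Krt15 stood at 7.78, 8.41 and 12.73 in syngeneic replicates 1 to 3; its change was 2.66 and 2.99 without replicates 1 and 2, and without replicate 3 it passed (5.10, adjusted p = 0.00209). The adrenal genes with the smallest p were Star (0.84 ± 0.29, adjusted p = 0.0844) and Cyp17a1 (-0.70 ± 0.25, adjusted p = 0.0898).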

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

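Counts of changed list members without each array were chosen only after the result was seen; the other alternatives were fixed earlier. With other normalizations, background correction, the deposited log2 values, other filters, floors, priors, array weights and thresholds, 3604 to 7110 probes were called, against 5075, and 12 to 16 lists, against 16. In each of these settings at least 99.96% of the probes called in the reported fit that were still tested kept their direction. Over all alternatives the 119 counted genes kept direction and side of the threshold in 1729 comparisons, lost the call in 387, gained one in 14 and reversed in 0. For lists these counts were 402, 29, 7 and 0. Since 108 of the 119 genes had passed the threshold in the same data, few reversals could be expected. Some list members short of the threshold changed sign, named here after their values were seen. Cd28 went from -0.31 to 0.61 without syngeneic replicate 2. Without syngeneic replicate 1, Cyp27b1 went from -0.31 to 0.37, Fgb from -0.19 to 0.59 and Masp1 from -0.18 to 0.52. Without 1 array the fit has fewer samples, and 1610 (without syngeneic replicate 2) to 6046 (without syngeneic replicate 3) probes were called, 627 to 3050 higher and 983 to 2996 lower, with 14 to 17 lists and an MHC-encoded median of 1.99 to 2.86. With the replicate number as a block, which costs residual degrees of freedom, 1886 probes (781 higher, 1105 lower) and 17 lists were called, with smooth and skeletal muscle added (camera adjusted p = 0.0442). Replicate numbers were not treated as pairs, since nothing stated that they pair animals. After removal of group means same-number arrays had correlations across probes of -0.00, 0.01 and 0.05. Tolerated replicate 1 correlated best with syngeneic replicate 2, while the value of 0.05, for replicate 3, was the highest of all combinations. With 3 centred values per group, these correlations cannot exclude pairing. With an estimated correlation camera called 0 lists. Estimated correlations of the tested lists ranged from -0.12 (smooth and skeletal muscle) to 0.83 (macrophages and dendritic cells), against the preset 0.01. Antigen presentation encoded outside the MHC lost its call at an estimate of -0.03, so a higher correlation alone does not account for the losses. Its unadjusted camera p was 0.0336 with the preset and 0.0898 with the estimated correlation. With an estimated correlation camera takes p from the few residual degrees of freedom of the arrays. A preset correlation uses the far larger number of genes instead, so an estimated one raises p by this alone. Without the filter the mean correlation within groups exceeded that between groups by 0.0480, against 0.0715; the cause was not tested. The 6 arrays allow only 10 splits into 3 and 3, too few for a share under 0.05; 1 split, the real one, reached 5075 probes, and the highest other called 0. Signal over background was not known for any probe, so the limit of detection could not be stated.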

Other observations

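All tests below, and the gene families, were chosen only after the result was seen; for the test of liver RNA in all syngeneic arrays this was the fall of Alb, before the values of its other markers were seen.

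In several families of transporters and metabolic enzymes more genes were lower than higher in tolerated grafts. Of 143 solute carrier genes (Slc) 61 were lower and 10 higher (median log2 fold change -0.67, camera adjusted p = 5.26e-05, and adjusted p = 0.252 with an estimated correlation), among them the amino acid transporter gene Slc7a13 (-4.95 ± 0.57, SE). Of 38 cytochrome P450 genes 15 were lower and 2 higher (median -0.94, adjusted p = 0.00341, and 0.252 with an estimated correlation), with Cyp2c11 (-4.61 ± 0.43) and Cyp2d2 (-4.04 ± 0.36) in front. Cyp2c11 and several other members of this family also belong to the lists of liver transcripts below, for which liver RNA in the syngeneic arrays was left undecided. Of 13 glutathione transferase genes 6 were lower (median -0.78, adjusted p = 0.00896, and 0.252 with an estimated correlation), with Gsta2 at -3.60 ± 0.35, and 6 were also lower with any 1 array left out. Aldehyde dehydrogenase genes did not pass camera (adjusted p = 0.0910). The lower Slc members numbered 37 without syngeneic replicate 2 and 42, 43 and 43 without tolerated replicates 2 and 3 and syngeneic replicate 1. The higher Slc members numbered 0, 2 and 2 without tolerated replicates 1 to 3, and 3, 1 and 18 without syngeneic replicates 1 to 3. The higher cytochrome P450 members numbered 1 without tolerated replicate 1, 0 without tolerated replicate 2 or 3 or syngeneic replicate 1 or 2, and 3 without syngeneic replicate 3.

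Respiratory chain genes were lower in 22 of 37 members (median -0.63, camera adjusted p = 2.08e-06, and adjusted p = 0.328 with an estimated correlation), among them Cox8b (-4.20 ± 0.40) and Ndufs1 (-1.34 ± 0.16). Ribosomal protein genes were higher in 32 of 41 (median 0.83, adjusted p = 2.09e-10, and 0.284 with an estimated correlation), with Rpl39 at 1.23 ± 0.20 and Rpl15 at 1.17 ± 0.19. Both depended on the scaling in size, with no change of sign: with median scaling 31 respiratory chain genes were lower (median -1.11) and 2 ribosomal genes higher (median 0.43), and with 75th percentile scaling 30 and 12. With 1 array left out the ribosomal count was 6, 3 and 5 without tolerated replicates 1 to 3, 4 and 1 without syngeneic replicates 1 and 2, and 33 without syngeneic replicate 3. The respiratory chain count was 4, 4 and 6 without tolerated replicates 1 to 3, 4 without syngeneic replicate 1 or 2, and 20 without syngeneic replicate 3. Potassium channels, olfactory receptors and proteasome subunits did not pass camera (adjusted p = 0.564, 0.338 and 0.269).

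The fall of proximal tubule genes was set against less cortex in the sampled tolerated pieces and against dilution of all kidney epithelium by infiltrating cells. Podocytes lie only in cortex, yet the median change of their genes lay 2.34 log2 units above that of proximal tubule genes (95% bootstrap interval over genes 1.72 to 3.20), which argues against less cortex as the whole cause. Genes of the loop of Henle, distal tubule and collecting duct lay 2.24 units above (1.76 to 3.19), which argues against dilution alone. The list medians were already known when both tests were chosen, so the direction of each difference was known beforehand. Both intervals cover the spread between genes and not that between grafts. How far other kidney cells express the listed podocyte genes was not determined. Lower expression in, or loss of, proximal tubule cells may remain, as a hypothesis that was not tested further.

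Albumin and other transcripts known from liver were set against liver RNA in the syngeneic samples. Over 25 tested liver markers without Alb the median change was -1.81 (95% bootstrap interval -2.78 to -0.80), with 8 lower and 0 higher, which left liver RNA in all syngeneic arrays undecided; how many of these genes kidney also expresses was not determined here. In syngeneic replicate 1 a second list of liver transcripts (37 of 55 tested) lay a median of 0.59 above the mean of replicates 2 and 3 (0.43 to 1.51), with 31 of 37 higher, while 10000 random lists of like level had a median of 0.02 and none reached it. The random lists were drawn gene by gene, whereas liver transcripts may vary together, so this comparison is too lenient to count by itself. Hp stood at 13.69, 8.84 and 10.34 in syngeneic replicates 1 to 3, Fgg at 12.99, 8.48 and 9.09 and Apoa1 at 11.07, 7.36 and 8.09, so that syngeneic replicate 1 may hold some liver RNA. Without that array Alb still fell (-7.05, adjusted p = 0.0227, against up to 0.0352 without any other array), so this alone does not account for the fall of Alb.

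Clock genes were set against a harvest at another time of day. Dbp (-2.62 ± 0.54), Tef (-2.78 ± 0.42), Nr1d1 (-2.11 ± 0.35), Nr1d2 (-1.21 ± 0.30), Per2 (-1.77 ± 0.38), Per3 (-1.88 ± 0.31) and Usp2 (-2.15 ± 0.55) fell, while Nfil3, of opposite daily phase, rose (2.34 ± 0.58) and Bmal1 had 1.45 ± 0.76 (adjusted p = 0.22). Only Tef passed with any 1 array left out, and Bmal1 passed without syngeneic replicate 3 (2.33, adjusted p = 0.0029, against up to 0.463 without another array). Dbp, Usp2 and Nfil3 had -3.23, -2.75 and 2.96 in that fit. The medians of the 2 sets differed by -4.00, but the genes were chosen after their values were seen and the opposite set held 2 genes, so this difference decides nothing. The hour of harvest is not given in the sources used here, and a difference in harvest time cannot be told apart from an effect of the graft's state on these genes.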
